A study of Mus musculus with 10 samples.

How the data were processed

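Samples were 10 cultures of Abelson virus-transformed B cell progenitors from E14.5 mouse fetal liver, 5 wild type and 5 with a homozygous Bim 3'UTR mutation, and groups and sample numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a miRNeasy kit, samples of low purity were left out, and an input of 100 ng was run on the nCounter. The labels do not say whether the samples of a genotype came from separate embryos, so p-values measure the spread between these samples, which may be partly technical.

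The deposited tables hold whole-number counts per probe, which the authors did not normalise as far as the values show: the control probes and library totals differ between samples, and the 2 tables hold the same values. Other steps of the authors' processing are not given in the sources used here. The table's own average, minimum, maximum and coefficient of variation columns were not used, since the average was a whole number only when multiplied by 12 lanes, while 10 samples are described. All 10 lanes carried the same cartridge identifier. Wild type samples lay in lanes 1 to 5 and mutant samples in lanes 6 to 10, so lane position and genotype cannot be told apart. The panel had 626 probes, with 566 for mouse miRNAs, 33 for viral miRNAs, 4 for housekeeping mRNAs, 8 negative controls, 6 positive controls, 3 positive and 3 negative ligation controls and 3 spike-in miRNAs. Viral probes served as a check of background: 1 of their 330 values exceeded the threshold. miR-543 had a count of 1 in all 10 libraries and miR-34c in 9, while the lowest count of every other probe was 3, so these counts of 1 look like a floor and neither probe was kept.

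A miRNA was detected in a library when its count exceeded the mean + 2 SD of that library's negative controls, a threshold of 90.5 to 127 counts. Probes above it in at least 5 libraries were kept, which left 116 of 566. Of the others, 404 exceeded it in no library, and 83 of the kept probes exceeded it in all 10. Counting error alone is 10.5% of a count at the lowest threshold and 1.00% at a count of 10000. Scaling factors from the positive controls ran from 0.910 to 1.08. Names follow the panel, and a probe joined by a plus sign covers more than 1 miRNA. Close relatives such as the let-7 and miR-30 members differ by few bases, and cross-binding of their probes could not be tested directly, because the tables hold no probe sequences (an indirect comparison, for neighbouring genes, is in the closing section).

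Kept counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors (0.872 to 1.11), a robust quasi-likelihood fit on genotype, and Benjamini-Hochberg adjustment at 0.05. Intervals are approximate 95% intervals from the fold change, its SE and 8 degrees of freedom, and values per group are mean ± SD of normalised counts. Lists of miRNAs were tested in camera of limma 3.58.1 with a preset correlation of 0.01 when they had at least 3 kept members, with an estimated correlation and fry as alternatives. Shares, totals and detected miRNAs were compared by exact two-sided permutation tests of the means, whose smallest possible p with 5 against 5 is 0.00794. Tests of the shares of 6 other probe groups and of single housekeeping mRNAs were not planned. Except for these and where said otherwise, the lists, tests, filter and alternatives were fixed before the data were examined. The lists were the miR-17~92, miR-106a~miR-363 and miR-106b~25 clusters, the miR-17, miR-18, miR-19 and miR-92 seed families, other miRNAs reported to target Bim, B-lymphoid, p53-responsive, let-7, miR-15/16, miR-29, miR-30, miR-232724, miR-221~miR-222, miR-99let-7miR-125 (without its let-7 members and miR-125a-3p), miR-183miR-96miR-182, miR-200, Dlk1-Dio3 and Sfmbt2 groups, and markers of other cell types.

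The text names every kept cluster miRNA, the 5 miRNAs with the smallest unadjusted p in each direction where fewer passed, the 10 with the highest mean, up to 4 members of a list past the threshold by p, and up to 4 members of each other list by mean count. That rule gave 46 miRNAs. Others are said to be chosen after their values were seen.

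Alternatives were scaling by DESeq2 (1.42.0) size factors, by the 100 highest miRNAs, by housekeeping mRNAs, by positive controls and by the total; no filter, a looser and a stricter filter; background subtraction; the DESeq2 Wald test; limma with voom weights; a fit without robust estimation; and leaving out each library. Leaving out pairs of libraries and leaving out 15 probes for fragments of ribosomal and transfer RNA were added after the data were seen. The edgeR test was tested on simulated data for 116 miRNAs, 20 of them changed, in 20 simulations. All changes were upward, counts were drawn independently, and both genotypes had the same spread. With the spread of all 10 libraries, the median estimated log2 fold change of the 2-fold changes was 0.854. With the spread of all 10 libraries it recovered 62.0% of 2-fold and 86.0% of 4-fold changes with 6.03% false calls, and with the spread of the wild type libraries 89.5% and 97.0% with 7.67%. Pairs of libraries were checked for duplicates by a chi-square test of their counts. The lowest chi-square per degree of freedom was 16.3, and 7.24 without the fragment probes, so no pair agreed within sampling noise. Repeat cultures or repeat runs of a sample could exceed that noise too, so the check does not show that the samples are independent. Which miRNA genes neighbour each other was read from a RefSeq gene table of assembly GRCm38.p6, in which 98 of the kept probes were matched. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the other tables and plots.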

Results

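The series profiled miRNAs in mouse B cell progenitors transformed with Abelson virus, a retrovirus carrying the v-Abl kinase that lets immature B-lineage cells grow in culture. The cells came from C57BL/6 fetal livers at E14.5. There were 5 wild type samples (1 to 5) and 5 samples homozygous for a mutation in the 3'UTR of Bim (6 to 10). Bim, also called Bcl2l11, is a pro-apoptotic BH3-only protein, and its 3'UTR holds sites for miRNAs of the miR-17~92 family. The labels do not say which bases the mutation changes. Bim mRNA was not analysed here, so the genotype labels could not be checked against it. The comparison asks whether the miRNA content of the cells differed between the genotypes, and in particular whether the miRNAs known to target Bim were present at similar levels.

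RNA was measured on a NanoString nCounter panel, which counts barcoded probes one molecule at a time after each miRNA has been ligated to a tag. The panel held 566 mouse miRNA probes. Wild type samples ran in lanes 1 to 5 and mutant samples in lanes 6 to 10 of a single cartridge, so an effect of lane position cannot be told apart from genotype. Total counts of all probes ran from 356141 to 470493 per library, and total mouse miRNA counts from 240469 to 354826. The mouse miRNA total was 254052 ± 10652 (SD, n = 5) in wild type and 296029 ± 45990 (SD, n = 5) in mutant samples, with an exact two-sided permutation p of 0.0952 for the difference of 41977. This result moved with the setting: the difference was 48497 (exact permutation p = 0.0476) after positive-control scaling, 53186 (exact permutation p = 0.0476) without mutant 6 and 27278 without mutant 9. Wild type libraries had 114 ± 12.2 miRNAs above background and mutant libraries 120 ± 9.87 (SD, n = 5 each; exact permutation p = 0.413). The remaining analysis used 116 miRNA probes above background in at least 5 libraries.

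The highest mean normalised counts over the 10 libraries belonged to miR-16, at 25429, and miR-142-3p, a miRNA restricted to blood cells, at 25049. Next came the probe shared by miR-20a and miR-20b at 17651 and the probe shared by miR-106a and miR-17 at 16603. They were followed by miR-2141, miR-720, miR-15b, miR-19a, let-7g and miR-1944, with means from 14083 down to 8204. miR-2141 and miR-720 are names given to fragments of ribosomal and transfer RNA. All 12 B-lymphoid and pan-haematopoietic miRNA probes on the panel were kept, though not above background in every library: miR-150 counted 60 and miR-155 counted 84 in wild type 5, below its threshold. None of 19 probes for markers of other cell types (erythroid, myeloid, endothelial, hepatocyte, mesenchymal, muscle and neural) was kept. Of their 190 values, 5 exceeded the background threshold of their library. These were miR-451 in wild type 4 (103 counts), miR-223 in wild type 4 (92) and mutant 10 (137), and miR-126-3p in mutant 6 (105) and mutant 10 (234).

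The clusters that target Bim were abundant in both genotypes, and the difference of their mean shares was smaller than the spread between mutant libraries. Together, miR-17~92 and its paralogous clusters miR-106a~miR-363 and miR-106b~25 took 21.1% ± 0.975 of miRNA counts in wild type and 21.4% ± 3.53 in mutant samples (SD, n = 5 each; exact permutation p = 0.849). The mutant libraries lay on both sides of the wild type range of 20.05% to 22.4%, at 24.3%, 24.4% and 23.1% in mutant 6, 7 and 8 and 17.9% and 17.3% in mutant 9 and 10. The miR-17~92 cluster promotes the survival of B cell progenitors. Its list, which includes the probes it shares with miR-106a~miR-363, took 17.5% ± 1.05 and 17.3% ± 3.57 (exact permutation p = 0.833, n = 5 each). Its share was 20.1%, 20.003% and 19.4% in mutant 6, 7 and 8 and 13.05% and 13.7% in mutant 9 and 10, against 16.5% to 19.1% in wild type. The probe shared by miR-20a and miR-20b had a log2 fold change of 0.01 (95% interval -0.23 to 0.25), mutant over wild type, and the probe shared by miR-106a and miR-17 had 0.02 (-0.29 to 0.33). For miR-19a the value was -0.06 (-0.30 to 0.18) and for miR-19b -0.01 (-0.21 to 0.19). The scarcer miR-18a (-0.17), miR-18b (-0.03) and miR-363 (-0.06) had wider intervals, the widest from -0.69 to 0.35 for miR-18a. miR-92a, the remaining member, counted 82 to 123 per library, above the threshold in 1 library, and was not tested. The shares therefore say little of miR-92a. Whether its low count reflects the cells or the probe cannot be told from these counts. Probes that cover 2 paralogs cannot assign their counts to either cluster. They were counted with miR-17~92 only, and miR-19b was counted in both lists. The kept members of the miR-106a~miR-363 list were miR-18b, miR-19b and miR-363.

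**Figure D1:**
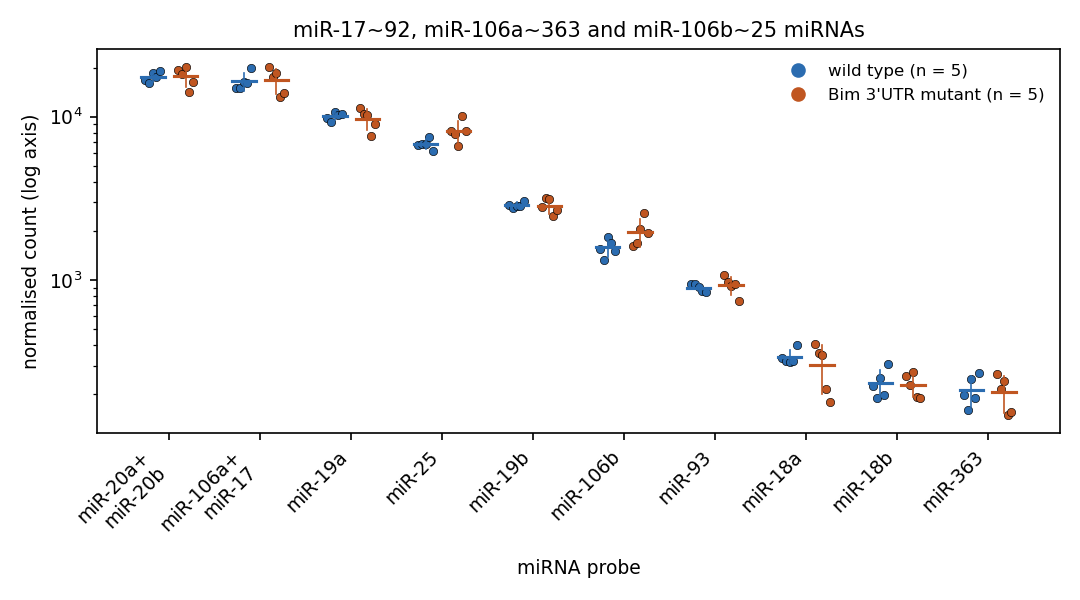
Normalised counts (log axis) of the 10 kept probes of the miR-17~92, miR-106a~miR-363 and miR-106b~25 clusters in 5 wild type (blue) and 5 Bim 3'UTR mutant (orange) libraries; points are libraries, horizontal lines means and vertical lines 1 SD. The groups overlap for every probe, with the mutant points of miR-25 and miR-106b lying higher on average.

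The miR-106b~25 cluster lay slightly higher in the mutant samples without passing the adjusted tests. It took 3.43% ± 0.229 of counts in wild type and 4.00% ± 0.511 in mutant samples (SD, n = 5 each; exact permutation p = 0.0476, Benjamini-Hochberg adjusted p = 0.349 over 8 shares). Its members miR-106b (log2 fold change 0.32, SE 0.15), miR-25 (0.27, SE 0.11) and miR-93 (0.05, SE 0.12) were all above 0. In edgeR the adjusted p was 0.373 for miR-25 and miR-106b over all miRNAs tested, and 0.276 for both when adjusted over the list alone. As lists, the 3 clusters together had a camera adjusted p of 0.831, with camera's direction up, a median log2 fold change of -0.00 and a mean of 0.03. This list passed with no filter (median 0.21, camera adjusted p = 0.0186) and with the looser filter (0.15, camera adjusted p = 0.0311), both of which add probes at background level to the comparison. The miR-17~92 list (median -0.01) and the miR-106a~miR-363 list (-0.03, 0 of 3 members above 0) had adjusted p values of 0.831 and 0.855, and the miR-106b~25 list (0.27, 3 of 3) had 0.412. The seed families gave the same picture. For the miR-17 seed the median was 0.04 with 4 of 4 members above 0 (adjusted p = 0.789). For the miR-92 seed it was -0.06 with a mean of 0.01 and 1 of 3 above 0 (adjusted p = 0.855), miR-32 at -0.17 being the member outside the clusters. The shares of the miR-17, miR-18, miR-19 and miR-92 seed families had exact permutation p values of 0.913, 0.563, 0.524 and 0.0873. No member of these lists passed in edgeR when adjusted over its list alone.

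Across the 116 miRNAs, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with 11 at an unadjusted p under 0.05 where chance gives 5.8. At that unadjusted threshold the count was 52 under housekeeping scaling and 23 under positive-control scaling, with 0 past the adjusted threshold in both. limma-voom also called 0. DESeq2 called 5, with miR-30d, miR-26b and miR-350 higher and miR-29b and let-7i lower in mutant samples. Without mutant 10, edgeR called 1, miR-29b, at a log2 fold change of -0.40. The median absolute log2 fold change was 0.19, and 111 of the 116 miRNAs had a fitted change within 2-fold. The 5 beyond it were miR-29c (2.10), miR-146a (1.70), miR-210 (1.46), miR-125a-3p (1.05) and miR-2132 (-1.16), named after their values were seen. A single library set some of them: miR-29c was at 0.22 and miR-146a at 0.76 without mutant 10, and miR-125a-3p was at -0.01 without mutant 9. On simulated counts for the 116 miRNAs, the test recovered 62.0% of miRNAs changed 2-fold and 86.0% of those changed 4-fold. Both genotypes were given the same spread there, taken from all 10 libraries. The real mutant libraries spread more widely than the wild type ones, so recovery in these data may differ.

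The miRNAs with the smallest p above and below 0 did not pass the edgeR test either. miR-30d had 392 ± 15.8 normalised counts in wild type and 561 ± 103 in mutant samples (SD, n = 5 each), a log2 fold change of 0.52 (95% interval 0.20 to 0.83; edgeR adjusted p = 0.250). miR-350 went from 547 ± 11.8 to 781 ± 179 (log2 fold change 0.51; edgeR adjusted p = 0.250). miR-26b, miR-1944 and miR-25 followed at 0.35, 0.29 and 0.27. Below 0, miR-29b, a miRNA reported to target Bim, had 1656 ± 33.6 and 1325 ± 174 (log2 fold change -0.32, -0.55 to -0.10; edgeR adjusted p = 0.250). The others were miR-1966 (-0.26), let-7i (-0.16), miR-1961 (-0.21) and miR-690 (-0.43), of which miR-1966, miR-1961 and miR-690 counted near background. For miR-30d, miR-350 and miR-1961 the wild type and mutant values did not overlap. Chance gives this for 0.794% of miRNAs, or 0.92 of those tested.

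**Figure D2:**
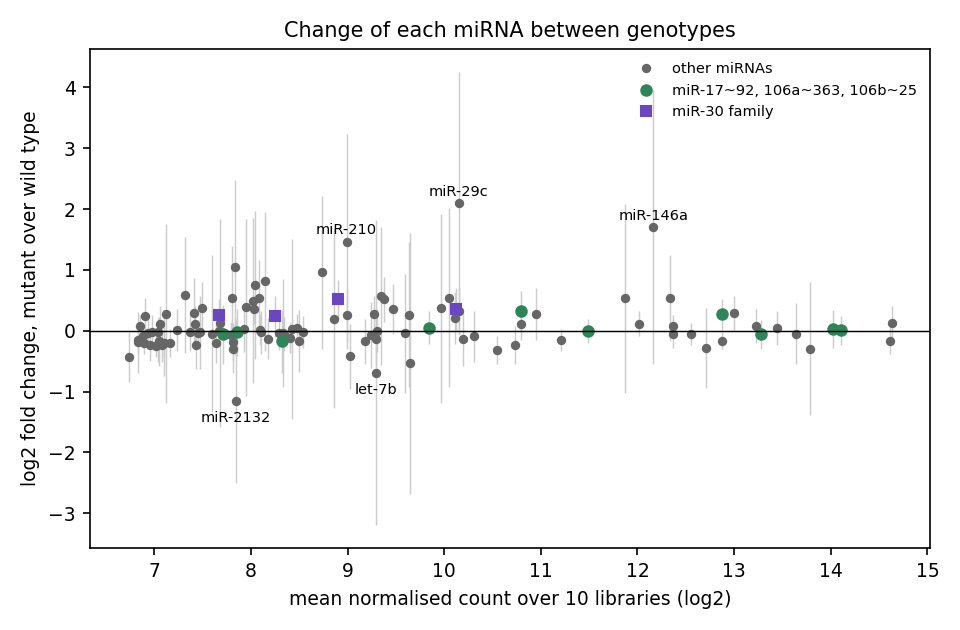
Log2 fold change of each of the 116 miRNAs, mutant over wild type, against its mean normalised count over 10 libraries (log2), with 95% intervals as grey lines. Cluster members (green) lie between -0.17 and 0.32 and miR-30 family members (purple) between 0.24 and 0.52, while miR-29c, miR-146a, miR-210, let-7b and miR-2132 have wide intervals.

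The miR-30 family was the only list of 13 to pass camera with a preset correlation, with an upward direction in mutant samples, and the call was lost with an estimated correlation (adjusted p = 0.610). No member passed over all miRNAs in edgeR with all 10 libraries, while DESeq2 called miR-30d, as did edgeR without mutant 6 and 7. All 4 kept members had values above 0: miR-30d (0.52), miR-30c (0.35), miR-30e (0.25) and miR-30b (0.24), with a median of 0.30 and an adjusted p of 0.00677 in camera (limma) with a preset correlation. The call was also lost in fry (adjusted p = 0.143) and without wild type 5 (median 0.21, adjusted p = 0.163). Over all alternatives the adjusted p ran from 0.000256 to 0.610. Adjusted over the list alone, 1 member passed, miR-30d.

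The other lists did not pass, and several held members that went both ways. Of the 9 let-7 and miR-98 probes, 3 were above 0 and 6 below (median -0.05; camera adjusted p = 0.684). Of the 4 most abundant members, let-7g (0.07), let-7a (0.08) and let-7d (-0.05) had intervals that include 0, and let-7i (-0.16, 95% interval -0.31 to -0.02) did not. let-7i did not pass in edgeR (adjusted p = 0.373) and was called lower by DESeq2. The miR-29 family had camera's direction down and a median of -0.24, from miR-29a (-0.24) and miR-29b (-0.32), against a mean of 0.51 set by miR-29c (2.10, or 0.22 without mutant 10); its adjusted p was 0.684, and 1 member, miR-29b, passed when adjusted over the list alone. Other miRNAs reported to target Bim had a median of -0.03 and a mean of 0.30, with camera's direction down (adjusted p = 0.831, 3 of 7 above 0), and included miR-181a at 0.54 (SE 0.31). B-lymphoid and pan-haematopoietic miRNAs had a median of 0.04 and camera's direction down (adjusted p = 0.932, 7 of 12 above 0), with miR-142-3p at -0.16, miR-16 at 0.13, miR-15b at 0.05 and miR-21 at -0.29. The miR-15/16 family had a median of 0.09 (adjusted p = 0.789), with miR-15a at -0.06 and miR-322 at 0.81 (SE 0.50). The miR-232724 clusters had a median of -0.15 (adjusted p = 0.697), with miR-27a at -0.15, miR-23a at 0.28, miR-23b at -0.18 and miR-24 at -0.03. In edgeR, apart from miR-29b, no member of these lists passed when adjusted over its list alone. Lists with fewer than 3 kept members were not tested. Among them, the p53-responsive miR-34a and miR-107 had -0.42 (SE 0.23) and -0.18, miR-200b had 0.01, miR-540-3p of the Dlk1-Dio3 imprinted cluster 0.50 (SE 0.59) and miR-466g of the Sfmbt2 intron cluster -0.21. The share of miRNA counts from all 51 Dlk1-Dio3 probes, not a planned test, was lower in the mutant. It was 0.801% ± 0.138 against 0.961% ± 0.0574 in wild type (mean ± SD, n = 5 each, exact permutation p = 0.0317, adjusted p = 0.190 over 6 shares). Only miR-540-3p of those probes was kept, and it went the opposite way, so this share is mostly background counts over the miRNA total. The total was 1.17 times as high in the mutant, and the sum of the negative controls 0.911 times. The Sfmbt2 share, also mostly of probes at background, had nearly the same ratio (0.834 against 0.833). A lower level of the Dlk1-Dio3 miRNAs is therefore not shown. None of the miRNAs listed for the miR-221~miR-222, miR-99let-7miR-125 and miR-183miR-96miR-182 clusters was kept. The miR-99let-7miR-125 list held miR-99a, miR-99b, miR-100, miR-125a-5p and miR-125b-5p, and left out let-7c, let-7e and miR-125a-3p of the same loci, which were kept. The abundant fragment probes miR-2141 and miR-720 had -0.30 (SE 0.47) and -0.05.

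The libraries differed more within the mutant group than within the wild type group. Pearson correlations of log2 counts across miRNAs ran from 0.919 to 0.993 between wild type libraries and from 0.839 to 0.986 between mutant libraries, and miRNAs are not independent replicates. Wild type pairs with wild type 5 lay at 0.919 to 0.945 and the other wild type pairs at 0.978 to 0.993. Mutant 6, 7 and 8 correlated with each other at 0.966 to 0.986, and the pairs that include mutant 9 or 10 at 0.839 to 0.935. The biological coefficient of variation was 25.5% in wild type and 47.9% in mutant samples. The following miRNAs were singled out after their values were seen. let-7b counted 26, 37 and 25 in mutant 6, 7 and 8, below their background thresholds, against 1209 and 1418 in mutant 9 and 10 and 456 to 899 in the wild type libraries. let-7c counted 96, 87 and 49 in mutant 6, 7 and 8, and 1663 and 1784 in mutant 9 and 10. miR-146a, a miRNA induced by NF-kB, counted 439, 1717 and 771 in mutant 6, 7 and 8, against 15130 and 21250 in mutant 9 and 10 and 1315 to 3292 in wild type. miR-29c reached 7665 in mutant 10. miR-210, a hypoxia-induced miRNA, counted 1092, 851 and 1403 in mutant 6, 7 and 8, 48 in mutant 9 and 388 in mutant 10. The same libraries differed in mRNA controls: B2m, the light chain of MHC class I, counted 1592, 1584 and 1490 in mutant 6, 7 and 8, against 4029 and 4195 in mutant 9 and 10 and 3250 to 4561 in wild type. Gapdh, a glycolytic enzyme, went the other way, with 1187, 1089 and 966 in mutant 6, 7 and 8, above the wild type maximum of 901, and 244 and 309 in mutant 9 and 10, below every wild type library. Between genotypes B2m did not differ beyond the spread (3733 ± 526 and 2578 ± 1402, SD, n = 5 each; exact permutation p = 0.135), nor did Actb (p = 0.286), Gapdh (p = 0.960) or Rpl19 (p = 0.230) in the same exact permutation test.

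**Figure D3:**
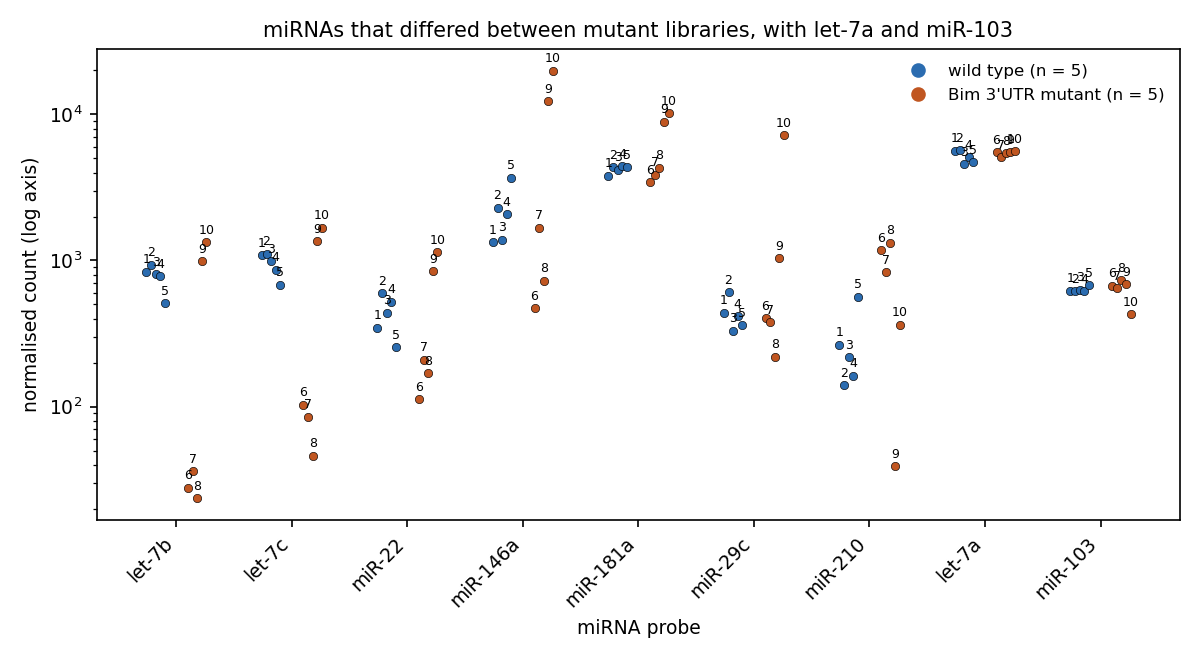
Normalised counts (log axis) of 7 miRNAs chosen after their values were seen, and of let-7a and miR-103, in the 5 wild type (blue) and 5 mutant (orange) libraries; each point is a library, with its number above. let-7b and let-7c lie lowest in mutant 6, 7 and 8, miR-146a and miR-181a highest in mutant 9 and 10, and let-7a lies close together in the 10 libraries.

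Leaving out mutant 9 and mutant 10 together, among all 20 pairs of libraries of a genotype left out in turn after the data were seen, edgeR called 6 miRNAs: let-7b, let-7c, miR-22, miR-29b and miR-804 lower and miR-210 higher in mutant samples. The scaling also matters for the sign of small changes. Scaling to the housekeeping mRNAs moved the median log2 fold change of all miRNAs to 0.46 and scaling to the positive controls moved it to 0.20, so the values above are changes relative to the typical miRNA. The miR-30 family and the miR-106b~25 cluster had medians above 0 under every scaling tried, while the miR-17~92, let-7 and miR-29 medians turned positive under housekeeping scaling. The miR-17~92 and let-7 medians also did so under positive-control scaling, and the miR-17~92 median was 0.00 when scaled to the 100 highest miRNAs.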

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

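Of the tests of explanations here, the estimated correlation and leaving out each library were planned, and the others (splits of the samples, probe binding, RNA fragments, other cell types and the spread of the groups) were set out after the results had been seen. A sample was singled out when its gap to the nearest other sample of its genotype, divided by the range of the group, exceeded Dixon's critical value of 0.71 for 5 samples. Chance does this in about 1 of 20 groups, so 6 of the 120 groups examined would be picked out, and 11 were. The groups are not independent, since miR-18a, for example, is also part of the miR-18 seed family share. Some samples can therefore be picked out more than once for the same counts.

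Wild type 5 accounted for 5 of the 11. It had the highest wild type miR-18a (402.9 normalised counts; others 315 to 336), the highest miR-1944 (9592; others 6575 to 7146) and the largest share of counts from the miR-18 seed family (0.257%; others 0.192% to 0.208%). It had the lowest miR-322 (92.9; others 221 to 250) and miR-34a (434; others 609 to 669). Wild type 4 had the most miRNAs above background (135; others 105 to 113). Mutant 8 had the lowest mutant miR-26b (240.3; others 295 to 312) and the highest Rpl19 count (5649; others 4518 to 4804). Mutant 9 had the lowest miR-16 (18862; others 27110 to 29386). Mutant 10 had the highest miR-29a (2101; others 1345 to 1542) and the highest miR-29c (7182; others 220 to 1036).

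The miR-30 family passed camera between genotypes with a preset correlation, and not with an estimated one (adjusted p = 0.610). Members that vary together between libraries are therefore a candidate explanation, and so is a single library, because the adjusted p was 0.163 without wild type 5. Chance is not excluded: 29 of 100 splits of the 10 libraries into 5 and 5, the real one included, gave at least the real count of 1 list, and the highest other split gave 4. Probes that bind more than 1 family member cannot be told apart from a change of all 4, since the tables hold no probe sequence, and a change with genotype stays open. For single miRNAs the splits decide nothing: the real count was 0 in edgeR (11 at unadjusted p under 0.05; 5 from DESeq2, 0 from limma-voom), which all 100 of 100 splits reach by construction, and the highest other split gave 3.

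Mutant libraries fell apart in their pairs with mutant 9 or 10, whose chi-square per degree of freedom was 253 to 445. Mutant 6, 7 and 8 differed from each other by 26.6, 89.1 and 111, below the highest wild type pair at 137. That pair includes wild type 5, and the highest wild type pair without it was at 80.1. An unequal amount of RNA or lane efficiency would scale all probes of a library alike. The chi-square is relative to library totals. Scaled to those totals, 21 to 28 miRNAs were over 2-fold apart between mutant 6, 7 or 8 and mutant 9 or 10. Wild type pairs had at most 19. B2m was higher and Gapdh lower in mutant 9 and 10 than in mutant 6, 7 and 8. These values argue against a common scale factor as the account of this split. Smaller effects of RNA amount or lane stay open. The measures tried for it (the ratio of ligation controls, the chi-square itself, and the miRNAs moving each way between 2 libraries of a genotype) were chosen after the results had been seen. Ribosomal and transfer RNA fragments do not account for the pattern, since without those probes the median stayed at 286.5 against a wild type maximum of 54.2. For the high miR-146a of mutant 9 and 10, RNA from erythroid, myeloid, endothelial, liver, mesenchymal, muscle or neural cells stays open: 2 of 19 probes of such cells exceeded background in mutant 10, miR-223 (137 counts, against 17 to 25 in the other mutant libraries) and miR-126-3p (234 counts), and 0 in mutant 9. Other lymphoid cells, separate embryos or transformed clones stay open too, as the labels do not tell these apart.

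The mutant group as a whole had a median SD of log2 counts of 0.30 against 0.18 in wild type, larger for 95 of 116 miRNAs, which is within what a chance division of the libraries gives (exact two-sided permutation p = 0.111).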

How the results depend on the processing

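No paired analysis was possible because the wild type samples are numbered 1 to 5 and the mutant samples 6 to 10. Limma on a normalised table was not run, since the deposited values are not normalised. The count of changed miRNAs stayed at 0 in edgeR under the 5 other scalings, 3 other filters, background subtraction, the fit without robust estimation and the fit without the fragment probes, and in limma-voom. The count at an unadjusted p under 0.05 was 11, and over these alternatives ran from 9 (scaling to the 100 highest miRNAs) to 52 (housekeeping scaling), with 23 under positive-control scaling; without a filter it was 49 of 566 and with the looser filter 34 of 282. The DESeq2 Wald test called 5, 3 higher and 2 lower. Leaving out each library gave 0 to 1 (miR-29b, lower, without mutant 10), and leaving out pairs of libraries gave 0 to 6, with calls for 4 of the 20 pairs; the cause was not tested. The count of lists was 1, and it became 3 without a filter and 3 with the looser filter, adding all 3 clusters, higher in the mutant, and the Dlk1-Dio3 cluster, lower (both at adjusted p 0.0186 and 0.0311). Both filters add probes at background level to the comparison. It became 0 with an estimated correlation, 0 with fry, 0 to 1 on leaving out each library (0 without wild type 5) and 0 in 7 of the 20 pairs. The share of counts from the 3 clusters differed by 0.289 percentage points, by -0.0386 after background subtraction, and by -0.457 to 1.32 on leaving out each library, all within the replicate spread. The miRNA total, 41977 higher in mutant samples, was 48497 higher after positive-control scaling (exact permutation p = 0.0476) and 27278 to 53186 higher on leaving out each library (p = 0.0476 without mutant 6). The number of detected miRNAs kept its direction and did not pass under any alternative. Below about 127 counts, background limits what the panel can show.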

Other observations

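The tests of neighbouring genes were chosen after the values were seen. Several miRNAs, most of them near background in most libraries, stood out in a few, and they are listed as values only. miR-296-5p counted 311, 170, 407 and 331 in mutant 6, 7, 8 and 10 and 21 in mutant 9, against 9 to 114 in wild type. miR-450a-5p, encoded near miR-322, counted 330 in mutant 10, where miR-322 counted 817, and 40 in mutant 9, where miR-322 counted 107. miR-150, a miRNA of mature lymphocytes, counted 961 in mutant 8 and 164 to 329 in the other mutant libraries, and 60 in wild type 5 against 292 to 522 in the other wild type libraries. miR-125a-3p had 962 normalised counts in mutant 9 and fewer in each of the other mutant libraries (lowest 90.0). miR-34c, a p53 target, counted 207 in mutant 8 and 1 in the other 9 libraries, where 1 looks like a floor.

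miRNAs whose genes lie within 10 kb of each other were compared in how they vary between libraries of a genotype. Over 41 such pairs among 98 matched miRNAs, the median correlation of deviations from the genotype mean was 0.696, against 0.198 for the 95th percentile of 10000 random sets of pairs (permutation p = 0.0001, the smallest these permutations can give). The 20 pairs among the seed families of the miR-17~92 and paralogous clusters had a median of 0.787. Of these, the 17 pairs from different seed families had 0.806 against 0.300 for random sets, which argues there against probes of near-identical miRNAs binding each other's targets. Shared local control of neighbouring genes, such as a common primary transcript, is a hypothesis for the miR-17~92 and miR-106a~miR-363 pairs. The miR-106b~25 pairs all lay below these medians. miR-106b with miR-93 had -0.316, miR-25 with miR-93 had 0.022 and miR-25 with miR-106b had 0.482. Pairs that share a miRNA are not independent, and the random sets were not matched for this. The permutation p-values for neighbouring genes are therefore likely too small. The deviations also carry the split of mutant 6, 7 and 8 from mutant 9 and 10. The miR-15/16 share, outside these clusters, split the same way (18.6%, 18.4% and 17.0% against 11.5% and 13.7%), while the let-7 and miR-98 share did not. An effect of proximity itself was not shown.

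Outside these clusters the picture differed. The 12 pairs from the same seed family had a median of 0.531 (random 95th percentile 0.337, permutation p = 0.0021), and the 9 from different families -0.298 (0.388). The former are neighbours and relatives at once. Their median cannot tell probes that bind each other's targets from shared local control. The 9 pairs from different families went both ways, so their median does not decide on such control. Above 0 were miR-425 with miR-191 (0.801), miR-27a with miR-23a (0.711) and miR-27b with miR-23b (0.082). The rest of the 9 were below 0, and most of those share the miR-24 probe. The highest pairs, let-7b with let-7c (0.990) and miR-29b with miR-29c (0.977), are of near-identical miRNAs. In all, 7 of the 41 pairs were below 0: miR-24 with miR-23b (-0.412), miR-27b (-0.412), miR-23a (-0.377) and miR-27a (-0.298), miR-125a-3p with let-7e (-0.394), miR-106b with miR-93 (-0.316) and miR-374 with miR-421 (-0.266).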
